A study of Caenorhabditis elegans with 2 samples.

How the data were processed

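The study measured, by ChIP-seq, where GFP-tagged ALY-1 was found on chromatin of early C. elegans embryos in 2 biological replicates of 1 group. Samples were grouped by the labels, which give the same strain, stage and antibody to both and number the biological replicates 1 and 2. Nothing in the labels ties them to separate days or batches. Only 2 replicates of 1 group exist here, so no test between groups was made. All p-values compare peaks or genes within these lists and do not measure variation between embryo cultures.

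The deposited files are peak lists in narrowPeak format on genome builds ce10 and ce11. Per the file listings deposited with each sample, each replicate has a list of peaks and background made as input for the irreproducible discovery rate (IDR) procedure, and the same single control alignment served both replicates. Per the same listings, a pooled list was called on both replicates together, and the final list is the optimal set passing IDR. Each of the candidate lists holds 30000 peaks. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each peak is a score the authors' peak caller gave, relative to the control in a way that is not stated. It was used only to rank peaks within a list. The deposited q-value column holds −log10 of the q-value and ranges from 0.0272 to 2.73 in the ce11 lists. The p-value column is filled with a placeholder in every list and was not used. The 881 thresholded ce11 peaks were checked to be the 881 with the highest signal in the pooled list, and the 894 ce10 peaks likewise. The median width of the thresholded peaks was 484 bp on ce11 (121 to 714 bp). Overlapping peaks with separate summits occur, and the 881 peaks cover 845 separate regions. Depth per sample is unknown, so the precision of a single peak could not be estimated. Intervals of shares are exact Clopper-Pearson and intervals of odds ratios are Woolf's, both at 95%, and they cover counting error only.

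Gene positions came from the Ensembl annotation of WBcel235, which has the coordinates of ce11, with 46890 genes on the 6 nuclear chromosomes, of which 19973 are protein-coding. Names of non-coding genes and tRNA isotypes came from the RefSeq annotation of the same assembly through WormBase identifiers. Lists on ce10 were used only for counts, replicate overlap and chromosome shares. No coordinates were converted. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end. Many worm genes are trans-spliced, so annotated 5′ ends can lie downstream of the start of transcription. Each summit was placed in the first of promoter window, exon, intron, 500 bp downstream of a gene end, or intergenic, using protein-coding genes. Weak peaks were the 28684 peaks of the pooled candidate list that overlap no thresholded peak. They were the background for peak-level tests because they were called in the same libraries. The pooled candidate list holds background as well as peaks, with −log10 q down to 0.0543 on ce11. Weak peaks can therefore include regions without binding. For the 29 gene lists, written out by name or biotype before the data were examined, the background was all protein-coding genes for protein lists and all annotated genes for RNA gene lists. Fisher's exact test was two-sided with Benjamini-Hochberg adjustment over lists, chromosomes, features or RNA gene classes. Replicate overlap (at least 1 bp) and promoter share were also set against 10000 rotations of the peaks along each chromosome, which keep their spacing. Intervals of Spearman's rho came from 2000 bootstrap samples of peaks. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

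The gene list test was tested on simulated data over 46890 genes. Planted lists were recovered in 80 of 80 cases. The planted share of members was above the bound share of every list here but tRNA genes, so recovery of weaker enrichment was not tested. With summits placed independently at random, the gene list test called 6 of 580 list tests (1.03%) and rotations called 0 of 29. Merging neighbouring genes into loci called 40 of 580 (6.90%), so that alternative is not calibrated and its values carry less weight.

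Genes given only to place a summit or qualify a count, or only under Other observations, were named after the data were seen. The other genes named in the text were fixed by rule before the data were examined. They were aly-1 and unc-119, genes at the 20 strongest thresholded peaks, up to 4 bound members of each list past the 5% threshold and up to 2 of each other list, by peak rank, and the 3 thresholded peaks with the greatest difference in rank between replicates. Alternatives fixed at the same time were the ce10 lists, other overlap rules and numbers of peaks, the stronger 440 thresholded peaks, each replicate's 881 strongest peaks alone, other promoter windows, assignment to the nearest 5′ end, 2 other backgrounds, rotations and merged loci. Alternatives and tests added after the data were seen were the counts per RNA gene class and their settings, leaving out peaks within 250 bp of a tRNA, snoRNA, snRNA, SL RNA, ribosomal, SRP or RNase P RNA gene, 10000 random draws of candidate peaks for the replicate overlap, a background without piRNA genes and summits within 250 bp of a gene. For RNA gene classes 100, 250 and 500 bp had all been looked at before 250 bp was used. No control sample without the tag was analysed here, so enrichment that does not depend on ALY-1 could not be measured.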

Results

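Binding of ALY-1 to the genome was mapped by ChIP-seq in early embryos of Caenorhabditis elegans. ALY-1 belongs to the Aly/REF family of nuclear proteins, adaptors that package messenger RNA for export from the nucleus. The embryos came from hermaphrodites of strain OP502, in which a transgene (wgIs502) supplies ALY-1 carrying GFP and FLAG at its C terminus, and they were taken 0 hours after synchronisation by egg bleaching. Chromatin was sheared by sonication and precipitated with an antibody against GFP. The 2 biological replicates form a single group, and no immunoprecipitation from worms without the tag was used here. Each replicate was represented by 30000 ranked candidate peaks and both together by a further 30000. From these the authors derived the optimal set passing IDR, 881 peaks on genome build ce11, called thresholded peaks below, and 894 on ce10. The question these lists can answer is which genes and regions carried the strongest ALY-1-GFP signal and whether both replicates ranked them alike. Read depth is unknown, because the files hold peaks and no read counts.

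The strongest ALY-1-GFP peaks lay at genes of small nucleolar RNAs, tRNAs and histones. Of the 20 peaks with the highest signal value, 11 had their summit within 250 bp of a small nucleolar RNA (snoRNA) gene, 4 within that distance of a tRNA gene and 3 at core histone genes. The snoRNA genes guide modification of ribosomal and other RNAs, and tRNA genes are transcribed by RNA polymerase III. The strongest peak (signal 643, V:12303455-12303826, ce11) covered the snoRNA genes C51F7.3 and C51F7.4 within an intron of frm-7 and ranked 1 and 2 in replicates 1 and 2. Its summit sequence, V:12303609-12303649, was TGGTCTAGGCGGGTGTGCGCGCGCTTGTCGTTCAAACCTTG and lay 30 bp inside C51F7.4. The peak ranked 2 (signal 642, IV:8334338-8335051) had its summit in the exon of the histone gene his-32, in the promoter window of his-31. The peak ranked 3 (signal 552, IV:11025899-11026373) covered the microRNA gene mir-51, with its summit 86 bp upstream of that gene and inside the non-coding RNA gene F36H1.17. The peak ranked 4 (signal 524, V:11314034-11314397) lay at the snoRNA gene T03F7.8 in an intron of cutl-18. The strongest peak at a tRNA gene ranked 5 (signal 491, X:13665413-13665773), with its summit 12 bp inside the leucine tRNA gene C04A11.t1. Its summit sequence, X:13665547-13665587, was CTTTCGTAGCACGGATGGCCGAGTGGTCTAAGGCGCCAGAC.

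Other snoRNA genes among these 20 were ZK265.10 (rank 6), W03C9.9 (rank 7), T06C12.16 (rank 8), Y43F8C.22 (rank 9), C04G6.12 in an intron of mpk-2 (rank 11) and C05D2.15 in an intron of madf-11 (rank 12). D1046.6 in an intron of cfim-2 (rank 14), ZK994.7 in an intron of pxn-1 (rank 15) and T02E1.9 (rank 19) completed the snoRNA genes. The summit ranked 14 lay inside D1046.t1, annotated as a pseudogene, 8 bp from its 5′ end, and 57 bp upstream of D1046.6. Pseudogenes were not among the classes counted. The promoter windows of the tRNA gene ZK994.t2 and the chemoreceptor gene sre-23 held the summits ranked 15 and 6, which lay closer to ZK994.7 and ZK265.10. The other tRNA genes were F15G9.t1 in an intron of him-4 (rank 13), F41D9.t3 in an intron of sulp-3 (rank 16) and F57F5.t1 (rank 18). The promoter windows of the protein-coding genes gcy-33 and cpr-9 also held the summit ranked 18, and that of T02E1.2 the summit ranked 19. The divergently transcribed histone genes his-59 and his-60 on chromosome IV held the summits ranked 10 and 17, near their 3′ ends. The peak ranked 20 had its summit in an intron of M01F1.8, 955 bp from the 5′ end of M01F1.9. In each replicate alone, these 20 peaks overlapped peaks ranked between 1 and 36.

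Counted over all 881 thresholded peaks, 168 (19.1%, exact 95% interval 16.5 to 21.8%) had a summit within 250 bp of a tRNA gene, against 0.798% of 28684 weak peaks. Weak peaks were those of the pooled candidate list that overlapped no thresholded peak, and they can include background regions without binding. The odds ratio was 29.3 (95% interval 23.7 to 36.2, Fisher's exact test, two-sided, adjusted exact p = 7.69e-150). For snoRNA genes the count was 64 (7.26%, interval 5.64 to 9.18%) and the odds ratio 16.6 (12.2 to 22.5, adjusted exact p = 1.89e-47). Core histone genes had 18 such peaks (odds ratio 22.1, 12.1 to 40.3, adjusted exact p = 4.66e-16). Genes of spliceosomal snRNAs and of the spliced leader (SL) RNAs had 12 (odds ratio 7.60, 4.04 to 14.3, adjusted exact p = 5.40e-07). The RNA genes of the signal recognition particle (SRP) and of RNase P had 5 thresholded and 2 weak peaks (odds ratio 81.9, 15.9 to 422, adjusted exact p = 5.57e-07). No thresholded peak lay at the 20 annotated ribosomal RNA genes, where the pooled list had 1 weak peak, so this class could not be compared. These class counts and the 250 bp distance were chosen after the data were seen.

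The share at RNA genes rose with rank. Among the 100 strongest peaks, 47 lay at tRNA genes and 32 at snoRNA genes, and 83 (interval 74.2 to 89.8%) lay at some RNA gene of the classes above. Of the peaks ranked 301 to 881, 9.64% lay at tRNA genes and 2.75% at snoRNA genes. Each replicate gave a like picture on its own. Of the 881 strongest peaks of replicate 1, 146 lay at tRNA genes and 57 at snoRNA genes, and of those of replicate 2, 167 and 66. Seen from the genes, 169 of 612 tRNA genes (27.6%, interval 24.1 to 31.3%), 59 of 346 snoRNA genes (17.1%) and 15 of 72 core histone genes (20.8%) had a thresholded summit within 250 bp. The summit lay inside the gene in 87 of the 168 tRNA peaks and in 12 of the 64 snoRNA peaks. The other 633 thresholded peaks had no gene of these tRNA, snoRNA, snRNA and SL RNA, ribosomal, SRP or RNase P RNA classes within 250 bp. Of these 633, 158 had another annotated non-coding RNA gene within that distance. These were microRNA, lincRNA, antisense RNA or other non-coding RNA genes (11, 6, 3 and 147 peaks, some counted in more than 1 type). The share of weak peaks near such genes was not counted, so no enrichment can be read from this count.

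**Figure D1:**
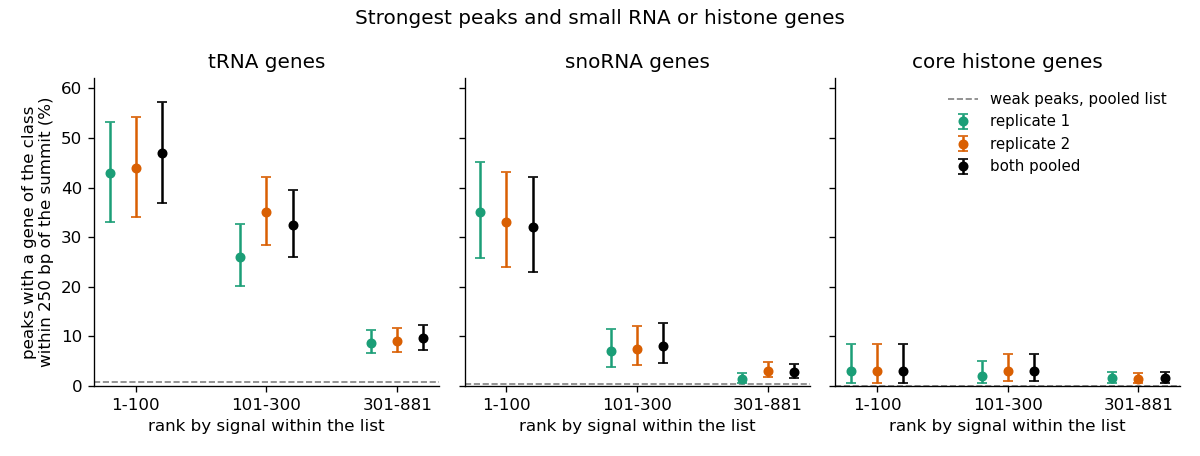
Share of peaks (y axis, percent) with a tRNA, snoRNA or core histone gene within 250 bp of the summit, by rank of signal within the list (x axis, 3 bins), for replicate 1, replicate 2 and both pooled; points are shares, bars exact 95% intervals, and the dashed line is the share among weak peaks of the pooled list. In the 100 strongest pooled peaks 47% lay at tRNA genes and 32% at snoRNA genes, against 9.64% and 2.75% in ranks 301 to 881.

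The 29 gene lists fixed before the data were examined also gave enrichment of tRNA, snoRNA, core histone and snRNA and SL RNA genes when a gene counted as bound if a thresholded summit lay from 1000 bp upstream to 200 bp downstream of its 5′ end. By this rule 6 lists were enriched and 2 depleted at a false discovery rate of 5% (Fisher's exact test, two-sided, Benjamini-Hochberg over 29 lists). The background of the RNA gene lists, all annotated genes, includes 15363 piRNA genes, of which 0.228% were bound. Of all other genes 3.31% were bound, so the piRNA genes raise the ratios of the enriched RNA gene lists. Of the tRNA genes 175 of 612 were bound (odds ratio 20.1, 16.7 to 24.2, adjusted exact p = 2.36e-138), led by C04A11.t1 and by the alanine tRNA genes F15G9.t1 and F15G9.t2 (rank 13, shared). Of the snoRNA genes 68 of 346 were bound (odds ratio 11.0, 8.39 to 14.5, adjusted exact p = 1.89e-41). Both calls held under all 12 alternatives, but the ratio varied, from 5.82 (merged loci) to 28.3 for tRNA genes and from 2.72 (merged loci) to 19.6 (observed over the mean of rotations) for snoRNA genes. Against genes with any pooled candidate peak the odds ratios were 9.01 and 5.11. Core histones had 16 of 72 genes bound (odds ratio 15.0, 8.50 to 26.3, adjusted exact p = 3.49e-12), led by his-31, his-60, his-59 and his-63. The summits assigned to these 4 genes lay in or beside the neighbouring histone genes his-32, his-59, his-60 and his-64, near their 3′ ends. For every other bound histone gene but his-4, the summit also lay nearest a different histone gene, 446 to 923 bp upstream of the assigned 5′ end. The summit of his-4 lay 153 bp inside that gene. The histone call was lost with a window of 500 bp upstream to 100 bp downstream (odds ratio 3.50, adjusted exact p = 0.174). It held under 12 of 13 alternatives, with adjusted p from 2.64e-17 to 0.174.

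Smaller enrichments were found for microRNA genes, snRNA and SL RNA genes and translation factors. Of 257 microRNA genes 23 were bound (odds ratio 4.24, 2.75 to 6.54, adjusted exact p = 2.24e-07), led by mir-51, mir-52 (rank 53), mir-62 (rank 245) and mir-80 (rank 267). Some shared a peak: mir-42, mir-43 and mir-44 that ranked 470, and mir-61 and mir-250 that ranked 491. The summits of mir-1829.3 and mir-5546 lay within 250 bp of a tRNA gene and a snoRNA gene. The test counts genes that share a peak as independent. Of 129 snRNA and SL RNA genes 9 were bound (odds ratio 3.20, 1.62 to 6.32, adjusted exact p = 0.0127). Among the 9 was mir-1831 (rank 489), a microRNA by name that the annotation types as a small nuclear RNA gene. The leading members were sls-2.4 (rank 124), sls-2.9 (rank 131, where a tRNA gene also lay within 250 bp), C28A5.7 (rank 171) and R07E5.16 (rank 342). Of 39 translation factor genes 4 were bound (odds ratio 5.80, 2.05 to 16.4, adjusted exact p = 0.0247). They were iff-2 (rank 260), eef-1A.2 (rank 309), eif-3.C (rank 400) and eif-2Bgamma (rank 489), the last through a peak at sup-39, annotated as a small nuclear RNA gene. These 3 calls depended on settings. The microRNA call held under 11 of 13 alternatives (adjusted p 7.47e-12 to 1), that of snRNA and SL RNA genes under 6 of 12 (1.21e-05 to 1) and that of translation factors under 6 of 13 (0.00277 to 0.435). Where the microRNA call was lost the odds ratio fell to 1.68 (the stronger 440 peaks) and 1.03 (merged loci), and it was 2.81 in replicate 2 alone, where the call held. The 6 settings that lost the snRNA and SL RNA call gave 1.14 (merged loci) to 3.08. Of the 7 that lost the call of translation factors, 3 gave 5.03 to 6.72, near the main value, and 4 gave 1.98 to 2.77.

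Depletion was found for piRNA genes and for chemoreceptor genes, a large family used mostly in sensory neurons. Of 15363 piRNA genes 35 were bound (odds ratio 0.0667, 0.0476 to 0.0934, adjusted exact p = 1.45e-132). The depletion was weaker against genes with any pooled candidate peak (odds ratio 0.305) and under rotations (0.302 times the mean, adjusted permutation p = 0.00193, over 12 alternatives 5.68e-193 to 0.00193). The members with the strongest peaks, 21ur-13979 (rank 74) and 21ur-5229, 21ur-356 and 21ur-11359 (rank 94, shared), had the summit within 250 bp of the snoRNA gene H09I01.2 or the tRNA gene B0350.t1. Of 1365 chemoreceptor genes 5 were bound (odds ratio 0.174, 0.0721 to 0.422, adjusted exact p = 1.89e-06), among them sre-23, sre-1 (rank 144), srh-269 (rank 334) and sri-5 (rank 390). The chemoreceptor call was lost against genes with any pooled candidate peak (odds ratio 0.685, adjusted exact p = 0.919) and under rotations (0.503 times the mean, adjusted permutation p = 0.308). It held under the other 11 of 13 alternatives (adjusted p over all 13 from 1.89e-12 to 0.919).

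The other 21 lists did not pass, and their small counts leave wide intervals. Cytosolic ribosomal protein genes, which RNA polymerase II transcribes strongly in most cells, had 3 of 80 bound (odds ratio 1.97, 0.619 to 6.27, adjusted exact p = 0.395), among them rpl-3 (rank 268) and rps-24 (rank 462). This list passed in replicate 1 alone (odds ratio 5.77, adjusted exact p = 5.46e-04; range over 13 alternatives 5.46e-04 to 1). Of 52 splicing factor genes 3 were bound, rsp-1 and rsp-2 through a shared peak at rank 226, and the list passed in replicate 2 alone (odds ratio 6.05, adjusted exact p = 0.00761; range 0.00761 to 1). Of 60 chaperone genes 4 were bound, led by dnj-29 (rank 110) and hsp-3 (rank 394), with an odds ratio of 3.62 (1.31 to 10.04, adjusted exact p = 0.0947). The list passed under rotations (adjusted permutation p = 0.0312; range 0.0312 to 0.788). No gene of the mRNA export and TREX list was bound, out of 15. The thresholded peak at aly-1, described below, had its summit outside the promoter window. None of 76 early zygotic regulators, 20 V-ATPase genes, 31 major sperm protein genes or 6 vitellogenin genes was bound.

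Among the remaining lists, 2 genes each were bound of 33 proteasome genes (pas-5 and rpn-7), 26 nucleoporin genes (npp-6 and npp-8) and 75 cell cycle and replication genes (cki-1 and efl-3). For the 57 maternal early embryo factors the count was 3, led by egg-5, whose peak lay at sls-2.4, and mex-1. A single gene was bound of 32 tRNA synthetase genes (ears-2, rank 98), 45 respiratory chain genes (cox-5B), 20 tubulin and actin genes (tba-2) and 63 homeobox genes (ceh-39). The last 5 counts were 3 of 269 nuclear hormone receptor genes (led by nhr-255 and nhr-48), 2 of 171 collagen genes (col-185 and col-44), 1 of 140 neuropeptide genes (flp-23), 3 of 322 F-box genes (led by fbxb-85 and fbxc-44) and 1 of 240 C-type lectin genes (clec-126). The summits assigned to nhr-255, col-185, flp-23 and clec-126 lay within 250 bp of a tRNA gene, and that of pas-5 near a snoRNA gene. That of col-44 (rank 836) lay in an exon of the neighbouring collagen gene col-9. For collagens the direction turned when summits were assigned to the nearest 5′ end (odds ratio 3.06, adjusted exact p = 2.21e-04; range over 13 alternatives 7.80e-07 to 1). Under 2 of 13 alternatives each, tubulins and actins passed as enriched (adjusted exact p over all 13 from 0.00773 to 1), and F-box genes (0.00156 to 1) and C-type lectins (0.0223 to 1) as depleted.

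**Figure D2:**
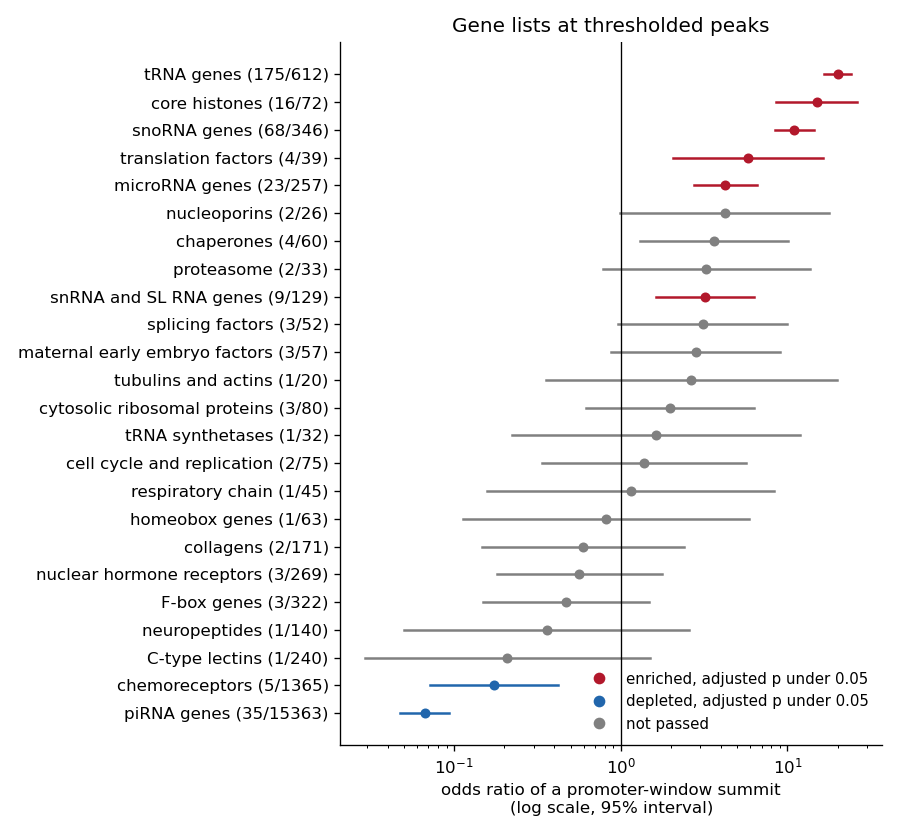
Odds ratio (x axis, log scale) of having a thresholded summit in the promoter window for the genes of each list against the other genes, with 95% intervals as lines; bound and total members stand in brackets, and the 5 lists with no bound gene are left out. The tRNA genes, core histones and snoRNA genes have the highest ratios (20.1, 15.0 and 11.0), and piRNA genes the lowest (0.0667).

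Relative to protein-coding genes, thresholded summits lay more often in promoter windows and after gene ends than weak peaks, and less often in exons. Of the 881 summits, 334 (37.9%, interval 34.7 to 41.2%) lay in the promoter window of a protein-coding gene, against 24.95% of weak peaks (odds ratio 1.84, 1.60 to 2.11, Fisher's exact test, two-sided, adjusted exact p = 1.62e-16). Rotating the summits along each chromosome gave a mean of 20.7% and at most 27.0% (one-sided permutation p = 0.0001, the smallest that 10000 rotations can give). A further 46 summits (5.22%) lay within 500 bp downstream of a gene end, against 2.82% (odds ratio 1.90, 1.40 to 2.58, adjusted exact p = 2.20e-04). Of these, 35 were among the stronger 440 peaks, and those ranked 5, 7 and 8 lay within 250 bp of a tRNA or snoRNA gene. Exons outside promoter windows held 108 (12.3%), against 29.2% (odds ratio 0.338, 0.276 to 0.414, adjusted exact p = 1.57e-31). Introns held 224 (25.4% against 26.6%, adjusted exact p = 0.462). Intergenic summits numbered 169 (19.2% against 16.4%, odds ratio 1.21, adjusted exact p = 0.0424), a call lost under all 3 alternatives (adjusted p 0.0769 to 0.142). Peaks near genes of the tRNA, snoRNA and other RNA classes counted above were then left out, a choice made after the data were seen. Of the remaining 633 summits, 280 (44.2%) lay in promoter windows. Summits after gene ends and in exons were not counted again in this way, so their part at RNA genes is unknown. The promoter counts include the summits of the bound histone genes, which for every such gene but his-4 lay nearest a different histone gene. Those ranked 2, 10 and 17 lay near the 3′ ends of these neighbours.

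Chromosome X carried more thresholded peaks than weak peaks did. It held 236 of 881 (26.8%, interval 23.9 to 29.8%), against 16.8% of weak peaks (odds ratio 1.81, 1.56 to 2.11, Fisher's exact test, two-sided, Benjamini-Hochberg over 6 chromosomes, adjusted exact p = 1.51e-12). Chromosome II held fewer, 121 (13.7% against 17.4%, odds ratio 0.758, 0.624 to 0.921, adjusted exact p = 0.0148), a call kept under 2 of 6 alternatives (adjusted p 0.0138 to 0.223). Chromosomes I, III, IV and V did not pass (odds ratios 0.945, 0.918, 0.857 and 0.815). V passed as depleted under 3 of 6 alternatives (adjusted p 3.62e-09 to 0.189), among them replicate 2 alone (0.739) and replicate 1 alone (0.668), and IV under 2 of 6 (adjusted p 8.88e-04 to 0.424). The tRNA genes, many of which lie on X, were bound at shares whose difference did not pass the test: 78 of 276 on X (28.3%) and 91 of 336 on the autosomes (27.1%) had a thresholded summit within 250 bp (odds ratio 1.06, 0.743 to 1.51, p = 0.785, Fisher's exact test, two-sided). With peaks near genes of the same RNA classes left out, X held 159 of 633 (25.1%, odds ratio 1.67, 1.39 to 2.01).

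**Figure D3:**
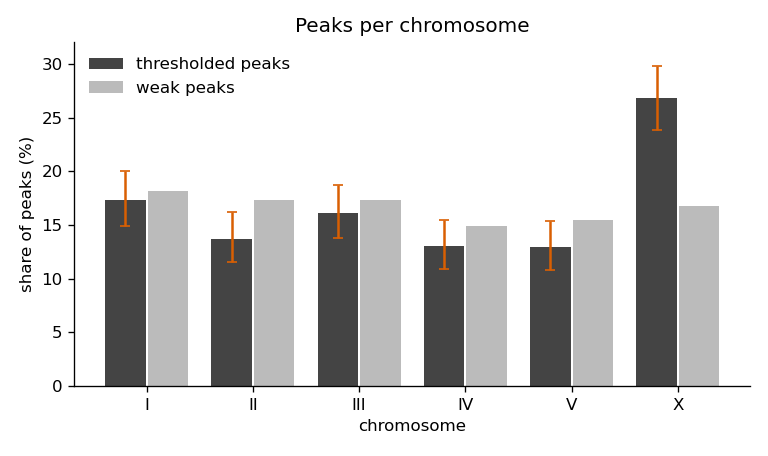
Share of peaks (y axis, percent) on each chromosome (x axis) for the 881 thresholded peaks (dark bars, lines are exact 95% intervals) and the 28684 weak peaks (light bars). Chromosome X holds 26.8% of thresholded and 16.8% of weak peaks.

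The strongest peaks of the replicates overlapped in part. Of the 881 strongest peaks of replicate 1, 482 (54.7%, interval 51.4 to 58.0%) overlapped 1 of the 881 strongest of replicate 2. Rotating the peaks of replicate 2 along each chromosome gave a mean of 0.888% and at most 15.4% (one-sided permutation p = 0.0001, the smallest possible). Drawing 881 of the 30000 candidate peaks of replicate 2 at random, a comparison added after the data were seen, gave a mean of 4.35% and at most 7.38% (one-sided permutation p = 0.0001). Neither comparison measures overlap that the shared control alignment could give. The overlap was 58.9% for the strongest 440 peaks and 51.7% for the strongest 1762. Of the thresholded peaks, 637 (72.3%) overlapped 1 of the 881 strongest of replicate 1 and 692 (78.5%) 1 of those of replicate 2. Both held for 479 (54.4%) and neither for 31 (3.52%). The thresholded peaks have the highest signal in a list called on both replicates together. Their overlap with each replicate is thus in part built in and is no independent measure of agreement. Across the thresholded peaks, Spearman's rho between the ranks in the replicates was 0.423 (bootstrap 95% interval 0.358 to 0.485). Peaks are not independent replicates, and these were selected by pooled signal, so this value describes these peaks and not all candidate peaks. The rank differed most at a peak in an intron of sax-7, a neuronal cell adhesion gene (IV:8066456-8066939, rank 26513 in replicate 1 and 219 in replicate 2). Next came a peak in an intron of ain-2 (I:4653969-4654452, ranks 13935 and 305) and an intergenic peak 1814 bp from the 5′ end of sid-3 (X:17184324-17184807, ranks 8669 and 241). All 3 ranked higher in replicate 2.

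**Figure D4:**
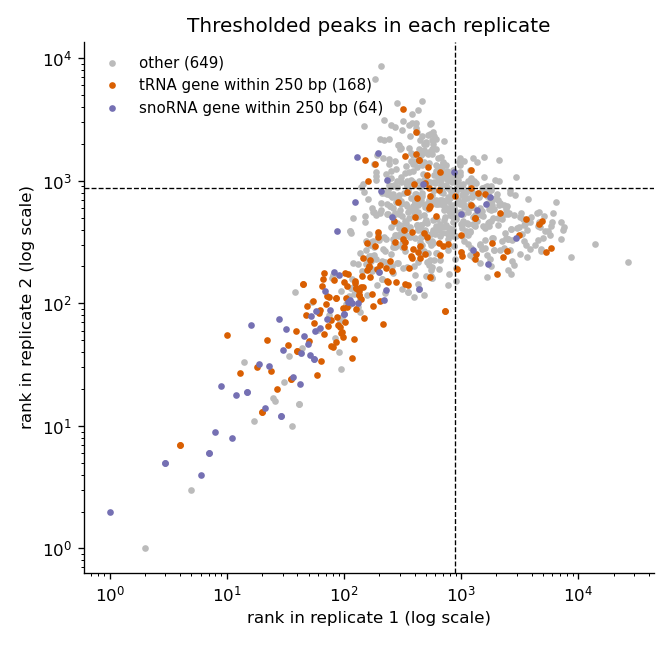
Rank of the strongest overlapping peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for each of the 881 thresholded peaks; orange points have a tRNA gene and violet points a snoRNA gene within 250 bp of the summit, and dashed lines mark rank 881. The points at the lower left rank high in both replicates, and of the 100 strongest pooled peaks 47 are at tRNA genes and 32 at snoRNA genes; 479 peaks lie within rank 881 in both.

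The locus of the tagged gene itself carried a thresholded peak. At aly-1 (IV:9108931-9109753, plus strand, ce11) the strongest pooled peak within 1000 bp ranked 427 (signal 106), with its summit 731 bp from the 5′ end, near the 3′ end of the gene. The locus ranked 459 in replicate 1 and 1737 in replicate 2. At unc-119 (III:10902641-10908935, plus strand), the gene mutated in strain OP502, the strongest pooled peak ranked 4061 (signal 54.5) and was not thresholded. Within 1000 bp of the gene, the strongest peak of replicate 2 ranked 2241, with its summit 950 bp from the 5′ end. That of replicate 1 ranked 12558 and was a different peak, with its summit 7270 bp from the 5′ end and past the 3′ end of the gene. The transgene adds copies of the aly-1 locus to the genome, which can raise the signal there without more binding. Its copy number and its other sequences are not given in the sources used here.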

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

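The X excess, the promoter share, the exon depletion, the 3′ end excess and the enrichment of all 5 RNA and histone gene classes with thresholded peaks kept their direction and their side of the threshold under every alternative run on them. The overlap of the strongest peaks of the replicates also kept its call, at 46.7 to 58.9%. Odds ratios ranged from 1.67 to 2.03 for X, from 24.0 to 50.4 for peaks near tRNA genes and from 11.7 to 29.6 for peaks near snoRNA genes, whereas the ratios for the lists of tRNA and snoRNA genes ranged from 5.82 to 28.3 and from 2.72 to 19.6. The settings for RNA gene classes, random candidate peaks in place of rotations, peaks near genes of the RNA classes left out, the background without piRNA genes and summits within 250 bp of the gene were chosen after seeing the data. Replicate support of the thresholded peaks fell with stricter matching. With summits within 100 bp it was 66.9% for replicate 1, 74.3% for replicate 2 and 47.2% for both, and with a reciprocal overlap of 50% it was 66.5%, 74.0% and 48.4%. The odds ratio of intergenic summits was 1.20 in the stronger 440 peaks (adjusted exact p = 0.142) and 1.17 to 1.18 without replicate 1 or 2, no longer past the threshold. Instead of 6 lists, 3 were enriched with the window of 500 bp upstream to 100 bp downstream and 3 with merged loci. Instead of 2 lists, 4 were depleted by the nearest 5′ end, and 1 each against genes with any pooled peak, under rotations and without piRNA genes as background, the last because the piRNA list itself is then left out. Collagens turned from an odds ratio of 0.594 to 3.06 with the nearest 5′ end and to 4.70 with summits within 250 bp of the gene, where peaks inside genes are counted. For the other changes the cause was not tested. Over all lists, 343 of 372 comparisons with the main value kept their side of the threshold, 18 lost a call, 9 gained one and 2 turned over. A further view of those 343 is that 34, called in neither setting, had an odds ratio on the other side of 1. For ribosomal RNA genes the ratio was 0 in the pooled list and in replicate 2, each with 1 weak peak, and undefined in replicate 1. This class was therefore left out of the ranges. Major sperm protein genes had no member with a pooled peak, so that background gave no value for them. No paired analysis was possible because there is only 1 group. The unknown read depth and the fixed 30000 candidates per list limit how far weaker binding could be ranked.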

Other observations

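Of the tests in this part, those of shared reads at tRNA genes without an identical copy, of GC content at tRNA and snoRNA genes, of RNA polymerase II transcription, of RNA genes on X, of the B box and of GC content away from those RNA genes, and the values for collagens, isotypes and snoRNA genes on X, were chosen only after the related results were seen.

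Peaks at tRNA genes were spread over the isotypes. Of 21 isotypes, cysteine (6 of 13 genes), glutamate (16 of 41) and alanine (13 of 34) had the highest shares of genes with a thresholded summit within 250 bp, and glutamine (3 of 27) was among the lowest. The shares did not differ beyond chance (permutation p = 0.63, 100000 permutations). No snoRNA gene on X had such a summit, a lower share than on the autosomes (p = 0.00258, Fisher's exact test, two-sided). By the promoter window rule F54E4.17 (rank 319) and K02B9.10 (rank 328) on X were bound, through summits farther than 250 bp from the gene. Collagen genes, which encode the cuticle, carried thresholded summits in exons more than in promoter windows. Of 171 collagen genes, 19 had a thresholded summit within 250 bp of the gene, but 5 of these summits, those of col-181, col-128, col-99, col-85 and col-72, lay within 250 bp of a tRNA or snoRNA gene. The other 14 were all in exons, led by col-108 (rank 212), col-83 (rank 331), col-44 (rank 454) and dpy-4 (rank 485), all chosen after their values were seen. With peaks near tRNA, snoRNA and the other RNA classes left out, the odds ratio against weak peaks was 3.04 (1.76 to 5.25, p = 4.38e-04, Fisher's exact test, two-sided). Compared within deciles of GC content it was 0.771 (0.441 to 1.35), and the median GC content at these 14 summits was 64.3%.

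The concentration of thresholded peaks at tRNA and snoRNA genes was in both replicates, with a lower odds ratio of 22.7 (18.8 to 27.3), so a single replicate did not make it. Compared within GC deciles the odds ratio was 24.9 (20.3 to 30.7), which argues against GC content. Strong transcription by RNA polymerase II stays open, since 3.75% (0.780 to 10.6%) of ribosomal protein genes were bound but 22.2% (13.3 to 33.6%) of core histone genes, against 28.6% (25.04 to 32.4%) of tRNA genes. Reads shared between identical gene copies may add to the tRNA signal. Genes of unique sequence had a peak less often (28 of 140) than genes with a copy (141 of 472, odds ratio 0.587, 0.371 to 0.928). Unique tRNA genes still had a peak more often than genes that are not tRNA genes (odds ratio 11.5, 7.59 to 17.6), which argues against shared reads alone. That ratio can count summits shared with a neighbouring copied tRNA gene, and its comparison genes include the rarely bound piRNA genes. Precipitation of such loci without the tag, near-identical tRNA copies and copies of snoRNA or core histone genes were not examined and stay open. The design, with 1 group, gives no biological contrast to set against them.

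The excess of thresholded peaks on X was in both replicates (lower odds ratio 1.72, 1.47 to 2.00). It persisted without peaks near genes of the tRNA, snoRNA and other RNA classes (1.67, 1.39 to 2.01), which argues against the many tRNA genes on X, and within GC deciles (1.75, 1.498 to 2.05). Untagged enrichment and a difference in chromatin between X and the autosomes stay open and were not tested.

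For the 633 thresholded peaks away from genes of those RNA classes, which include 158 near other non-coding RNA genes, unrecognised genes resembling tRNA genes were tested through the B box, an internal promoter element of tRNA genes with the core GTTCGANNC. The core lay within 100 bp of the summit in 68.5% of tRNA peaks and 25% of snoRNA peaks, but in 16 of these 633 (2.53%). Among weak peaks away from those RNA genes the share was 1.76%, with an odds ratio of 1.10 within GC deciles (0.658 to 1.83). This argues against genes with this exact core as the explanation for the group. Genes with another form of the box, or without one, were not searched for. The peaks ranked 3, with its summit in the non-coding RNA gene F36H1.17 (IV:11025899-11026373), and 22, in K10H10.14 (II:14496921-14497155), were among the 16. A candidate explanation is GC-rich sequence, since signal rose with GC content across 29245 pooled peaks away from those classes (Spearman's rho 0.333), which are not independent replicates. Median GC content was 51.5% at the 633 peaks and 42% at weak peaks, and whether this reflects binding or library preparation was not tested.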
